A study of Mus musculus with 10 samples.

How the data were processed

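The data are p65 ChIP-seq libraries from Tconv and Treg of C57BL/6 mice, unstimulated or stimulated for 3 h on plates coated with antibody against CD3 with soluble antibody against CD28, per the labels' protocols. There were 8 immunoprecipitated libraries in 4 groups of 2 and 2 input libraries of chromatin mixed from both cell types, stimulated and unstimulated. Nuclear lysates were sonicated and precipitated with an antibody against p65, and libraries were amplified over 12 PCR cycles, per the labels' protocols. The culture conditions of the unstimulated cells were not given in the sources used here.

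Trim Galore 0.4.1, BWA 0.7.15-r1140, MACS2 2.1.1.20160309 and the genome build mm10 are named in the submitters' processing notes. The deposited peak lists have no header; their names describe peaks of pooled replicates without blacklisted regions, kept by a conservative test of reproducibility between replicates (IDR), so each list gives 1 set of peaks per group and none per library. How the input libraries entered the peak calling is not given in the sources used here. The fold enrichment of each summit over its local background is the authors' ratio as the peak caller gave it. The −log10 p and −log10 q of each summit are likewise the authors' deposited values. The deposited score of each summit equals 10 times its −log10 p, without decimals, in 100% of entries (within 1 unit). These values were used to describe, rank or filter peaks within a list. The lists give no read numbers, so the depth of each library is unknown, and a deeper or cleaner library would give a longer list and higher folds and −log10 p. Closer agreement between the libraries of a group could also lengthen its list, since reproducible peaks alone were kept, and that agreement cannot be seen here.

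Overlapping entries of a list were merged into regions, each with its strongest summit, which joined several summits in 5.47% to 14.7% of regions. A region had a counterpart where a region of the other list overlapped it by at least 1 bp. Shares carry 95% Wilson intervals over regions, which are neither replicates nor independent. Shifting 1 list circularly along each chromosome 100 times gave the overlap of unrelated lists, with means of 0.246% to 1.14% of regions. For the combinations of lists, all 4 lists were merged.

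Genes came from RefSeq's table for assembly GRCm38.p6, which has the coordinates of mm10; 21883 protein-coding genes were used. The table gives gene starts and ends but neither strand, transcription start sites nor exons, and no genome sequence was used. The design fixed before the data were examined assigned regions to the nearest transcription start and tested sequence motifs. Instead, each region was assigned to the protein-coding gene whose body was nearest to its strongest summit (inside counts as 0, ties by the nearer gene end), within 50 kb. Position was given as within 1 kb of a gene end, inside a gene, outside a gene within 50 kb, or farther, with the start and the end of a gene not told apart. Motifs, exons and introns were not analysed here.

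Position was compared between regions with and without a counterpart within a list by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over 8 tests. The 17 gene lists (387 genes, each matched to the table) were fixed before the data were examined. For each list, the number of genes with a region was set against 10000 random lists matched on deciles of the length of genome assigned to a gene. The percent of regions without a counterpart was set against 10000 random lists drawn from genes with a region in either list of the pair and matched on their number of regions. Lists with fewer than 5 regions got no percentile. A list was said to stand apart at or above the 97.5th or at or below the 2.5th percentile. Chance puts about 5% of lists there, and no p-value is given across genes. The Treg identity list shares 6 genes with the co-stimulation list, 3 with the cytokine receptor list, 2 with the chemokine receptor list and 1 with the naive list.

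Genes were named by a rule fixed before the data were examined. For each comparison, these are the genes of the 5 regions with the highest fold enrichment without a counterpart in each direction, and of the 5 strongest shared regions. Up to 3 genes were added from each of the NF-kB, Treg identity, early activation and effector cytokine lists. Some genes that this rule names are not reported here. Foxp3, Il2ra, Ctla4, Rel, Nfkb1, Nfkbia, Tnfaip3 and Il2 are given in all lists. The further members of the Treg identity list in the stimulated comparison were chosen after their values were seen.

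Simulated lists holding 20, 50 or 80% of the 11077 stimulated Treg regions, moved by up to 100 bp, were recovered at 20.0, 50.0 and 80.0%. The narrowest of these regions spans 218 bp, so such moves keep an overlap, and the recovery checks the code alone. On 300 regions, overlaps and gene assignments had 0 disagreements with a brute-force search. A gene list set to 75% of regions without a counterpart in simulated data was found in 100% of 20 runs of the stimulated Treg against Tconv comparison, and 5.38% of the 260 unchanged list results fell outside the central 95%. These runs do not give the rate of chance calls in the data, where the share without a counterpart varied with the strength of regions.

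The alternatives were a reciprocal overlap of 50%, summits within 200 bp, the upper 50% of each list, equal lengths of 2961 regions by fold enrichment or by −log10 p, and the strongest 2961 regions against a full list. For regions gained on stimulation, the 5734 strongest regions of each stimulated list by fold enrichment were also set against full unstimulated lists. For position and gene lists they were gene ends within 2.5 kb, all gene biotypes, distances of 10 and 200 kb, every gene within 50 kb, and random lists without matching. A common cut-off at a −log10 p of 38.1 and assignment to the nearest gene end were added after the data were seen. So was an adjustment for strength, in which the share expected from the fold enrichment of the regions, in 50 equal parts of a list, was subtracted for the list and for the random lists. Between the cell types, lists were also set against 10000 draws of single regions matched on the same parts, chosen after the data were seen, which take no account of several regions at 1 gene. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.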

Results

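Binding of p65 (RelA), a subunit of the NF-kB transcription factor, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in T cells from the spleens and lymph nodes of C57BL/6 mice. The cells were conventional T cells (Tconv) and regulatory T cells (Treg), the T cell subset that restrains immune responses. Each was taken unstimulated or after 3 h with antibodies against CD3, the signalling part of the T cell receptor, and CD28, a co-stimulatory receptor. The series has 10 libraries, with 2 for each of the 4 immunoprecipitated groups and 2 of pooled input chromatin. The authors' peak lists hold 1 list per immunoprecipitated group, made from both libraries together, so no spread between replicates can be given, and the intervals below cover counting error over regions alone. The depth of the libraries is unknown. The Tconv culture received IL-2 at 2 ng/ml and the Treg culture at 10 ng/ml, so the cell type and the IL-2 concentration changed together in the stimulated samples. The culture and IL-2 of the unstimulated cells were not given. Differences between stimulated and unstimulated lists therefore cannot be told apart from effects of IL-2 or of the culture itself.

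After overlapping entries were merged, the unstimulated lists held 2961 regions in Tconv and 3208 in Treg, and the stimulated lists held 5734 in Tconv and 11077 in Treg. Merging all 4 lists gave 11923 regions. The most frequent combination was the stimulated Treg list alone, with 4899 regions, followed by both stimulated lists without either unstimulated list, with 3274. Regions present in all 4 lists numbered 1644, and 475 were present in both unstimulated lists and neither stimulated list. The lists end at different strengths: the lowest −log10 p, as the authors' peak caller gave it, was 13.3 in unstimulated Tconv, 15.1 in unstimulated Treg, 38.1 in stimulated Tconv and 26.6 in stimulated Treg.

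**Figure D1:**
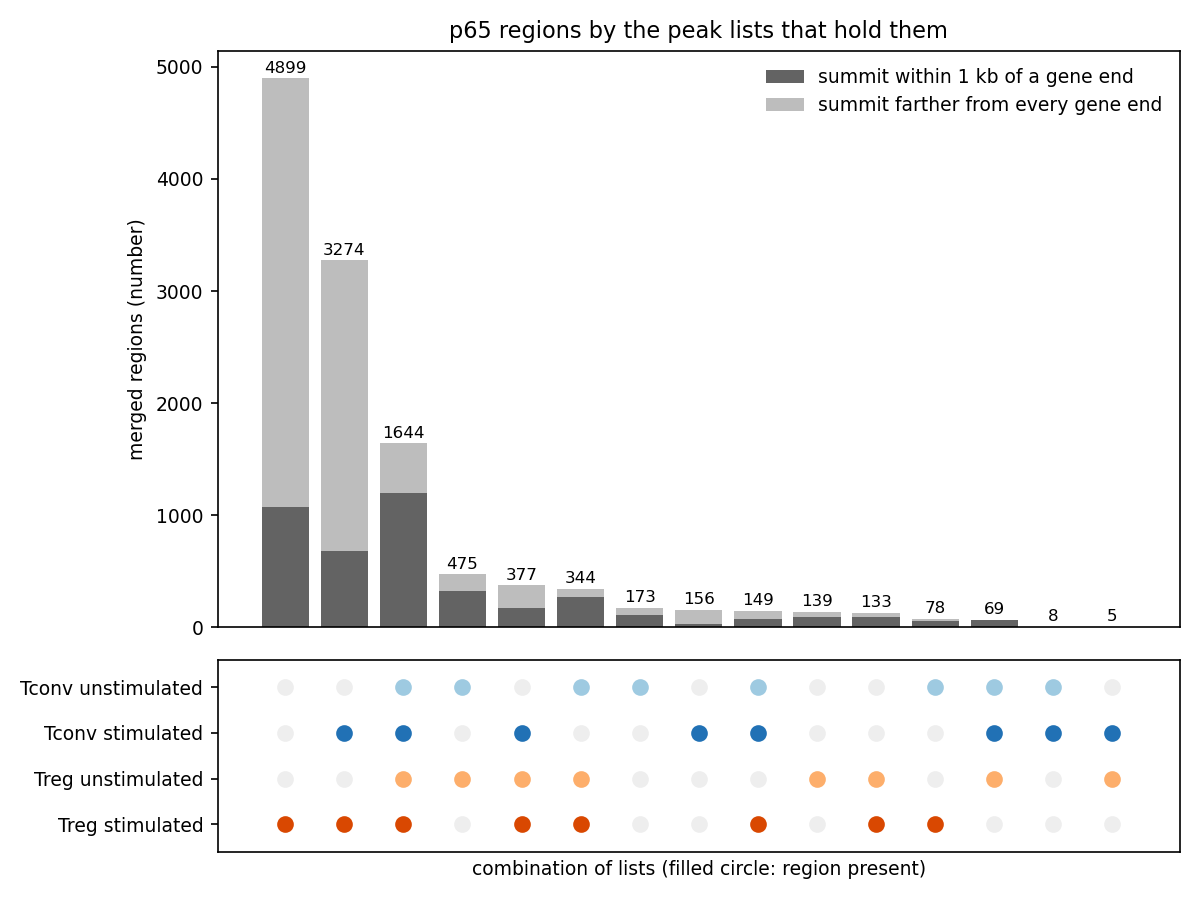
Number of merged p65 regions (vertical axis) for each of the combinations of the 4 peak lists, shown by filled circles under the bars; dark grey marks regions whose summit lies within 1 kb of a protein-coding gene end. The stimulated Treg list alone holds 4899 regions and all 4 lists share 1644.

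The first comparison asked where p65 was bound after stimulation of Tconv. Stimulated Tconv had regions at NF-kB feedback genes already bound without stimulation, and regions without an unstimulated counterpart near genes such as Cxcr5, Egr2, Tnf and Icos. Of the 5734 stimulated regions, 3866 (67.4%, 95% Wilson interval 66.2 to 68.6%) had no counterpart in the unstimulated list. In the other direction, 1075 of the 2961 unstimulated regions (36.3%, 34.6 to 38.1%) had no stimulated counterpart, a share that was 18.5% at a common −log10 p cut-off and 62.4% with equal list lengths. The strongest shared regions lay at Nfkbia, which encodes the inhibitor IκBα (82.3-fold over the local background in the stimulated list), at Tnfaip3, which encodes the deubiquitinase A20 (70.2-fold), at Nfkbid (69.8-fold), and inside Exoc2 (66.3-fold) and Hivep2 (61.6-fold). The strongest stimulated regions without an unstimulated counterpart lay beside Hspb7 (66.3-fold), inside Cxcr5, a follicular homing receptor (63.8-fold), inside Lrrfip1 (62.4-fold), and outside Spry1 (61.4-fold) and Gadd45b (55.6-fold). Among the fixed gene lists, such regions were found inside Rel (37.2-fold) and at Nfkbiz (34.9-fold) of the NF-kB genes, and inside Egr2 (48.7-fold), outside Egr1 (43.1-fold) and inside Nfatc1 (42.0-fold) of the early activation genes. They were also found at Tnf (50.9-fold), outside Tnfsf8 (36.0-fold) and 21.8 kb outside Ifng (28.0-fold) of the cytokine genes, and inside Icos (46.0-fold), Irf4 (36.3-fold) and Il2ra (34.8-fold) of the Treg genes. The strongest unstimulated regions without a stimulated counterpart lay at Kpna1 (41.1-fold), inside Snx29 (37.9-fold), and at Lrba (23.3-fold), Tbc1d20 (21.8-fold) and Pink1 (21.8-fold).

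By gene list, 26 of the 32 NF-kB family and feedback genes had a stimulated Tconv region and 25 had an unstimulated one, where random lists matched on territory had medians of 6 and 4. Of the early activation genes, 28 of 30 had a stimulated region and 15 an unstimulated one. The Treg identity genes had a region at 19 of 38 genes after stimulation and at 5 before. Of the 44 stimulated Tconv regions near Treg identity genes, 42 (95.5%) had no unstimulated counterpart, at the 99.9th percentile of random lists (median 79.5%), although assigning each region to every gene within 50 kb gave the 93.8th percentile. Near the NF-kB genes the share was 55.7% (34 of 61 regions), below all 10000 random lists, but at percentile 16.8 of random lists drawn without matching on the number of regions. Of the 28 unstimulated regions near NF-kB genes 1 had no stimulated counterpart (percentile 0.005; 6.84 at a common −log10 p cut-off), of the 18 near early activation genes 0 (percentile 0.035), and of the 8 near T cell receptor signalling genes 0 (percentile 1.62; 28.7 with equal list lengths). The last 2 lists held too few such regions for a percentile at the common cut-off. Co-stimulation and TNF receptor genes (92.9%, 39 of 42 regions, 99.0th percentile) and survival genes (93.3%, 28 of 30, 98.9th percentile) also stood above random lists. The call for the survival genes ended with equal list lengths (percentile 95.4), with distances of 10 kb (96.8) and 200 kb (97.3) and at the common cut-off (91.1).

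The same comparison in Treg gave a larger list of stimulated regions, at many of the same kinds of genes. Of the 11077 stimulated Treg regions, 8564 (77.3%, 76.5 to 78.1%) had no counterpart in the unstimulated list, and 693 of the 3208 unstimulated regions (21.6%, 20.2 to 23.1%) had no stimulated counterpart, a share that rose to 35.2% with a reciprocal overlap, 48.4% in the upper 50% of each list and 74.8% with equal list lengths. The strongest shared regions lay inside Nfkbia (101.6-fold), inside Cd2, an adhesion receptor (96.5-fold), inside Nr4a1, an immediate-early nuclear receptor gene (95.3-fold), outside Cish, a feedback inhibitor of cytokine signalling (93.3-fold), and outside Tpst2 (92.8-fold). The strongest regions without an unstimulated counterpart lay 47.4 kb outside Rasgrp1 (99.6-fold), beside Hspb7 (97.45-fold), inside Zap70, a T cell receptor kinase gene (90.2-fold), and outside Gadd45b (89.5-fold) and Spry1 (86.1-fold). From the fixed lists, they included regions inside Rel (61.2-fold), at Nfkbiz (47.6-fold) and at Otulin (43.7-fold), inside Egr2 (69.8-fold), Nr4a2 (65.2-fold) and Nfatc1 (58.3-fold), at Tnf (81.2-fold), outside Tnfsf8 (58.9-fold) and 21.8 kb outside Ifng (34.7-fold). The Treg identity genes gave regions inside Icos (72.4-fold), inside Itgb8, an integrin gene (63.0-fold), and outside Irf4 (56.5-fold). Unstimulated regions without a stimulated counterpart lay at gene ends of Lipt2 (24.6-fold), Pink1 (22.2-fold), Nop56 (21.02-fold), Dip2a (20.7-fold) and Ankrd26 (20.3-fold).

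All 30 early activation genes and 34 of the 38 Treg identity genes had a stimulated Treg region, against 18 and 10 in the unstimulated list, and 28 of the 32 NF-kB genes had one, against 24. Near NF-kB genes 60.0% of the 85 stimulated regions had no unstimulated counterpart, below all 10000 random lists (median 84.2%; percentile 3.54 without matching). Of the unstimulated regions, 0 of 33 near NF-kB genes (percentile 0.045; 3.06 adjusted for the strength of the regions), 0 of 25 near early activation genes (0.375), 0 of 20 near cytokine receptor and STAT genes (0.79) and 0 of 15 near naive and conventional T cell genes (1.98) lacked a stimulated counterpart. A common −log10 p cut-off ended the calls for the early activation (percentile 3.29) and cytokine receptor genes (28.4), and random lists without matching those for the cytokine receptor (3.32) and naive genes (4.49). The call for the naive genes also ended with equal list lengths (4.97), every gene within 50 kb (2.67) and a distance of 10 kb (2.82), and these genes held too few regions for a percentile at the common cut-off. Near early activation genes 78.8% of the 118 stimulated regions had no unstimulated counterpart (percentile 0.92). This call ended at a distance of 10 kb (percentile 3.75), with every gene within 50 kb (70.8), without matching (67.4), at a common −log10 p cut-off (10.6) and adjusted for strength (5.90). Near Treg identity genes 93.2% of the 162 stimulated regions had none (percentile 97.9; 96.1 at a distance of 10 kb). The survival genes stood higher, at 93.8% of 65 regions (percentile 98.7), but not with equal list lengths (88.7), at 200 kb (96.1) or at the common cut-off (95.9).

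Stimulated regions lay away from gene ends more often than unstimulated ones. A summit within 1 kb of a protein-coding gene end was found for 72.2% of unstimulated Tconv regions (70.6 to 73.8%) and 70.4% of unstimulated Treg regions (68.8 to 72.0%), against 39.1% (37.9 to 40.4%) and 33.0% (32.1 to 33.9%) after stimulation. Shifted lists gave 3.17 to 3.26%. Within stimulated Tconv, 23.3% of regions without an unstimulated counterpart and 71.8% of those with one lay near a gene end (odds ratio 0.119; two-sided Fisher's exact test, p = 1.35e-274, Benjamini-Hochberg adjusted over 8 tests 5.42e-274). Within stimulated Treg the shares were 22.4% and 69.2% (odds ratio 0.128), with a p too small for the test's arithmetic. Unstimulated regions with and without a stimulated counterpart did not differ detectably in Tconv (72.4% and 71.9%; exact p = 0.765, adjusted 0.851) or in Treg (70.5% and 70.1%; exact p = 0.851, adjusted 0.851). Between the cell types, unstimulated Treg regions without a Tconv counterpart lay near a gene end in 56.6% of cases and those with one in 74.0% (odds ratio 0.458, exact p = 1.51e-17, adjusted 3.01e-17), and unstimulated Tconv regions in 62.0% and 73.9% (odds ratio 0.576, exact p = 1.08e-06, adjusted 1.72e-06). For stimulated Treg regions the shares were 27.5% and 38.3% (odds ratio 0.611, exact p = 9.90e-34, adjusted 2.64e-33), and for stimulated Tconv regions 41.6% and 39.0%, which did not differ detectably (exact p = 0.456, adjusted 0.608). These tests compare regions of the lists, which are not replicates of a condition.

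**Figure D2:**
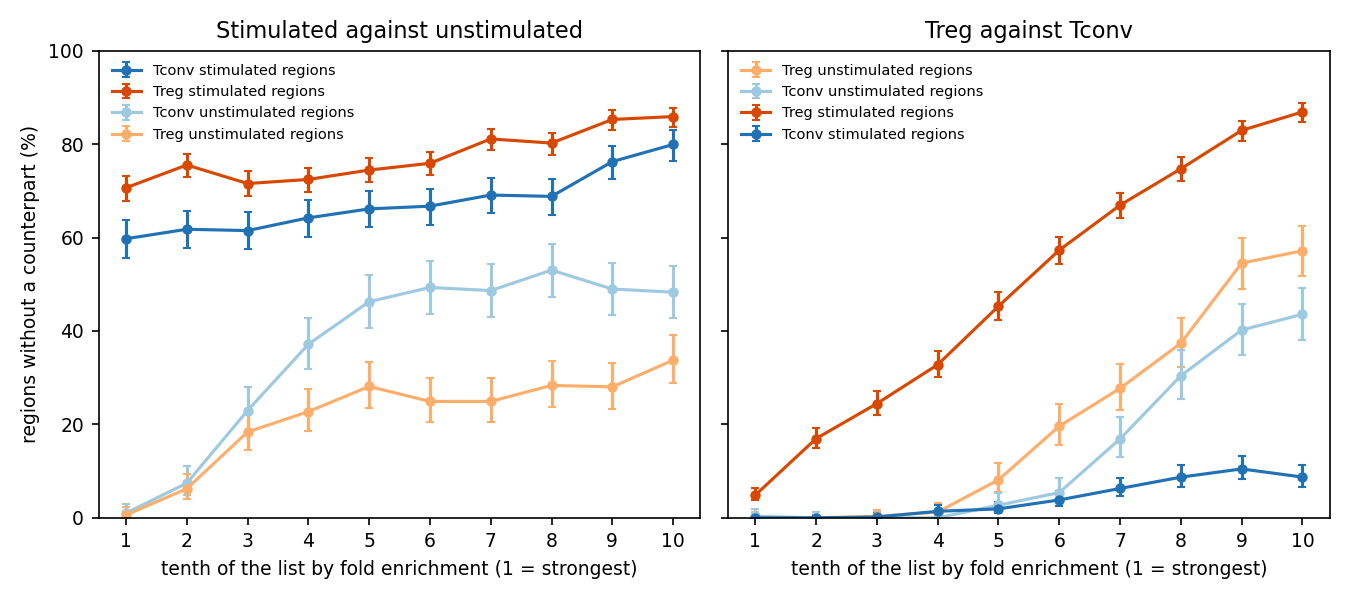
Percent of regions without a counterpart in the other list (vertical axis) by each of 10 equal parts of a list ranked on its own fold enrichment (horizontal axis, 1 is the strongest); points are shares and bars 95% Wilson intervals. Of stimulated Treg regions without a stimulated Tconv counterpart, the share runs from 4.87% in the strongest part to 86.9% in the weakest, while without an unstimulated Treg counterpart it runs from 70.7% to 85.9%.

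Without stimulation, Treg and Tconv shared most p65 regions, and the shared regions were the strong ones: 0 of the 321 strongest Treg regions and 1 of the 297 strongest Tconv regions (0.337%, 0.0595 to 1.88%) lacked a counterpart. Of the 3208 Treg regions 661 (20.6%, 19.2 to 22.0%) had no Tconv counterpart, and of the 2961 Tconv regions 413 (13.9%, 12.7 to 15.2%) had no Treg counterpart (7.18% at the common cut-off). Shared regions were led by those within 1 kb of a gene end of Sugp2 (92.4-fold in the Treg list), Phf12 (84.1-fold), Rab3gap2 (77.0-fold) and Rab35 (70.7-fold), and by a region inside Nadk, 1.41 kb from its nearer end (72.2-fold). Treg regions without a Tconv counterpart were led by Sdhaf1 (12.1-fold), Fnbp1 (11.1-fold), H2-Q4 (11.1-fold), Apobec3 (10.5-fold) and Enpp3 (9.96-fold). Tconv regions without a Treg counterpart included those of Kpna1 (41.1-fold), Sirt5 (9.60-fold), Zfp408 (8.86-fold) and Nxf1 (8.68-fold). The fixed lists added Treg regions without a Tconv counterpart 1.53 kb outside Bcl3 (7.30-fold), 24.5 kb outside Nfkbia (6.80-fold) and at Tnip1 (6.29-fold). They also added regions 10.7 kb outside Atf3 (9.59-fold) and at Bhlhe40 (7.30-fold) and Gadd45b (7.30-fold), 9.16 kb outside Klrg1 (7.50-fold), inside Il2ra (6.72-fold) and 2.02 kb outside Tnfrsf18, which encodes the receptor GITR (6.14-fold).

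The Treg identity genes held few unstimulated regions, and those in Treg were weak, with a median of 6.04-fold against 8.30-fold in the whole list. Of these, 8 of 12 (66.7%) had no Tconv counterpart, at the 99.9th percentile of random lists and the 98.5th adjusted for strength, but at the 94.8th of draws of single regions matched on fold enrichment. Survival genes (5 of 7 regions, 98.6th percentile), cytokine receptor and STAT genes (9 of 20, 98.5th percentile) and T cell receptor signalling genes (6 of 12, 97.9th percentile) also stood above random lists. In the other direction, the naive and conventional T cell genes (8 of 18 Tconv regions without a Treg counterpart, 99.8th percentile) and chemokine receptor genes (5 of 9, 99.9th percentile) did so, and these lists share 3 genes. Adjusted for strength, the calls for cytokine receptor genes (percentile 95.8) and naive genes (96.7) ended, and in the matched draws they lay at 95.5 and 91.7, survival genes at 98.3, T cell receptor genes at 97.65 and chemokine receptor genes at 98.0. At a distance of 10 kb the calls for cytokine receptor genes (percentile 95.7) and T cell receptor genes (91.1) ended and the chemokine receptor genes held too few unstimulated Tconv regions for a percentile, while with every gene within 50 kb the call for survival genes ended (94.4). At a common −log10 p cut-off these lists either held too few regions for a percentile or, for cytokine receptor genes, no longer stood apart (47.7).

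After stimulation, p65 regions near genes of the Treg program were present in Treg and absent from Tconv more often than regions near other genes. Of the 11077 stimulated Treg regions 5463 (49.3%, 48.4 to 50.2%) had no Tconv counterpart, while 238 of the 5734 stimulated Tconv regions (4.15%, 3.66 to 4.70%) had no Treg counterpart. Both shares depend on how far down each list is read: at the common cut-off they were 38.1% and 11.5%. With equal list lengths they were 30.8% and 31.5%. Equal lengths make both shares nearly equal by construction, so that setting cannot show whether they differ. The 2961 strongest Treg regions against the full Tconv list gave 14.3%. Near Treg identity genes 118 of 162 regions (72.8%) had no Tconv counterpart, above all 10000 random lists (median 50.7%), and 15 of the 38 genes had a region in stimulated Treg and none in stimulated Tconv, while 19 had a region in both and 4 in neither. The region counts at these 15 genes, in Treg, were 21 for Ikzf2, which encodes the transcription factor Helios, 9 for Rora, 7 for Itgb8, 6 for the cytokine gene Il10, 3 each for Nrp1 and Plagl1, 2 each for Foxp3, Ikzf4, Lrrc32, Entpd1, Nt5e, Klrg1 and Gzmb, and 1 each for Tnfrsf4 and Socs2. Icos had 7 Treg regions and 2 Tconv regions, Tigit 6 and 1, and Cd83 8 and 1. Prdm1 had 4 in each. Genes with a region in Treg alone were not particular to the Treg identity list, since the Treg list is the longer one. Of the 42 ribosomal protein genes, a control list, 8 had a region in Treg alone, 10 in both and 24 in neither. Of the NF-kB genes 2 had one in Treg alone and 26 in both, and of the naive genes 0 and 21.

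The strongest Treg regions without a Tconv counterpart lay inside Itgb8 (chromosome 12, 119235596 to 119236721 of mm10, 63.0-fold), inside Tnfrsf8, which encodes CD30 (54.0-fold), inside Mdfic (49.2-fold), inside Nxpe3 (45.9-fold), and 16.4 kb outside Ikzf2 (chromosome 1, 69703341 to 69704321, 44.8-fold). The Treg list added a region 29.9 kb outside Lrrc32, which encodes the TGF-β docking receptor GARP (40.3-fold), and regions inside Foxp3 (32.1-fold) and Il2ra (31.9-fold). The NF-kB list added regions inside N4bp1 (18.8-fold) and at Nfkbid (17.9-fold) and Ikbke (12.8-fold). The early activation list added regions 21.6 to 47.1 kb outside Dusp4 (27.0-fold), Bhlhe40 (19.4-fold) and Zfp36l1 (17.7-fold), and the effector list regions outside Tnfsf8 (22.7-fold) and Ifng (19.5-fold). Tconv regions without a Treg counterpart were led by Enc1 (17.8-fold), Spring1 (15.4-fold), Vdac1 (15.4-fold), Foxp1 (15.2-fold) and Skor1 (15.1-fold). The strongest shared regions were those of Nfkbia, Rasgrp1, Hspb7, Cd2 and Nr4a1 (95.3- to 101.6-fold in the Treg list).

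Regions near NF-kB genes were shared more often than random: 21 of 85 Treg regions (24.7%) had no Tconv counterpart (percentile 0.01, median 49.4%), a call that ended with equal list lengths (percentile 29.3). Early activation genes (36.4% of 118 regions, percentile 0.49) also stood below random lists, though not with every gene within 50 kb (percentile 4.61), without matching (6.20) or adjusted for strength (40.2). Below random lists were also naive and conventional T cell genes (40.2% of 199, percentile 1.68) and chemokine receptor genes (35.5% of 62, percentile 2.44). The call for the naive genes ended in 6 of the 8 alternatives (percentiles 2.94 to 20.05) and that for the chemokine receptor genes in all 8 (3.79 to 35.1). In draws of single regions matched on fold enrichment, NF-kB genes lay at percentile 2.91, naive genes at 22.8, early activation genes at 78.1 and chemokine receptor genes at 15.5, while Treg identity genes (100), co-stimulation genes (100) and survival genes (99.6) lay above the central 95%. Cytokine receptor and STAT genes (41.7% of 120 regions, percentile 4.93; below random lists at a distance of 10 kb, percentile 1.795), T cell receptor genes (43.3% of 171, 6.06), effector cytokine genes (42.9% of 28, 25.8), co-stimulation genes (58.3% of 103, 89.2) and survival genes (52.3% of 65, 62.2) lay within the central 95% of random lists. So did class I antigen presentation genes (53.3% of 15, 61.0), the ribosomal control (45.5% of 22, 44.7), the liver and neuron control (37.5% of 8, 23.3) and erythroid and endothelial markers (3 of 6 regions, 46.0).

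**Figure D3:**
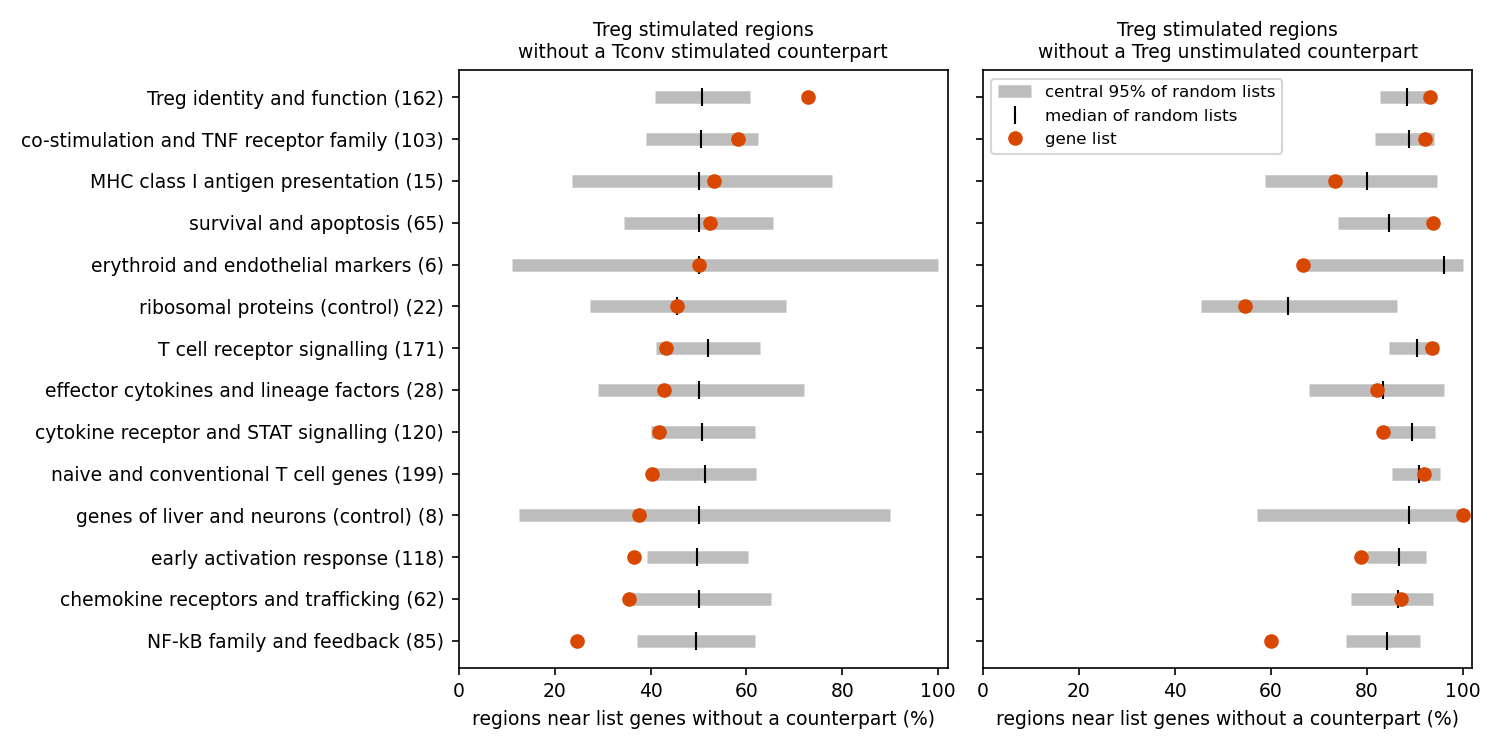
Percent of stimulated Treg regions near the genes of each fixed list (number of regions in parentheses) without a counterpart in stimulated Tconv (left) or unstimulated Treg (right); grey bars span the central 95% of 10000 random gene lists and ticks their medians. Treg identity genes sit at 72.8% on the left, above their grey bar, and NF-kB genes at 24.7%, below it.

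Foxp3, Il2ra and Ctla4 had more regions in stimulated Treg than in stimulated Tconv, and Il2 fewer. More regions per gene are common in the stimulated Treg list, which holds 11077 against 5734. Nfkbia, Tnfaip3, Rel and Nfkb1 also had more regions there. Foxp3, which encodes the lineage factor of Treg, had regions in stimulated Treg alone: 1 inside the gene, 4.47 kb from its nearer end (chromosome X, 7583694 to 7584964, 32.1-fold), and 1 whose summit lay 0.204 kb outside it (7578796 to 7580036, 14.8-fold). Regions assigned to neighbouring genes are not counted here. Among them, a stimulated Treg region of 30.8-fold lay inside Ppp1r3f, beside Foxp3 (7570574 to 7571384). Il2ra, which encodes the α chain of the IL-2 receptor, had 11 regions in stimulated Treg, 6 in stimulated Tconv, 1 in unstimulated Treg and 0 in unstimulated Tconv. Its strongest region lay inside the gene in both stimulated lists (chromosome 2, 11650884 to 11654118 in Treg, 62.9-fold, and 34.8-fold in Tconv). A stimulated Treg region (11621227 to 11624174, 12.0-fold) overlapped 1 of the 6 Tconv regions but was not assigned to Il2ra, so it is not among the 11. Ctla4, an inhibitory receptor gene, had 8 regions in stimulated Treg, 1 in stimulated Tconv and 0 in the unstimulated lists; the shared region lay 0.088 kb outside the gene (chromosome 1, 60908359 to 60909521, 31.3-fold in Treg and 11.7-fold in Tconv). Il2 had 2 regions in stimulated Tconv and 1 in stimulated Treg, which was shared, between 26.5 and 31.2 kb outside the gene. Some of these Treg regions lay below 38.1, the lowest −log10 p of the stimulated Tconv list. They were the Ctla4 regions at 37.0, 28.2 and 33.9, the Il2ra regions at 26.7 and 29.0, and the Il2 region at 30.4. Both Foxp3 regions lay above it.

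Nfkbia, Tnfaip3, Rel and Nfkb1 had a region near a gene end in all 4 lists. Nfkbia had a region inside the gene in each (33.2-fold in unstimulated Tconv, 82.3-fold in stimulated Tconv, 42.3-fold in unstimulated Treg and 101.6-fold in stimulated Treg; chromosome 12, 55488620 to 55493567 in the last). Tnfaip3 had a summit within 0.1 kb of the gene in each (35.1-, 70.2-, 43.3- and 86.1-fold in the same order), Rel one within 0.1 kb (24.7-, 44.7-, 33.0- and 44.7-fold) and Nfkb1 one inside the gene, 0.409 to 0.437 kb from its end (14.8-, 52.0-, 18.2- and 64.2-fold). Folds of different lists are not on a common scale, since each depends on the depth of its own libraries. A further region 16.5 kb inside Rel was present in both stimulated lists (37.2- and 61.2-fold) and in neither unstimulated list.

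**Figure D4:**
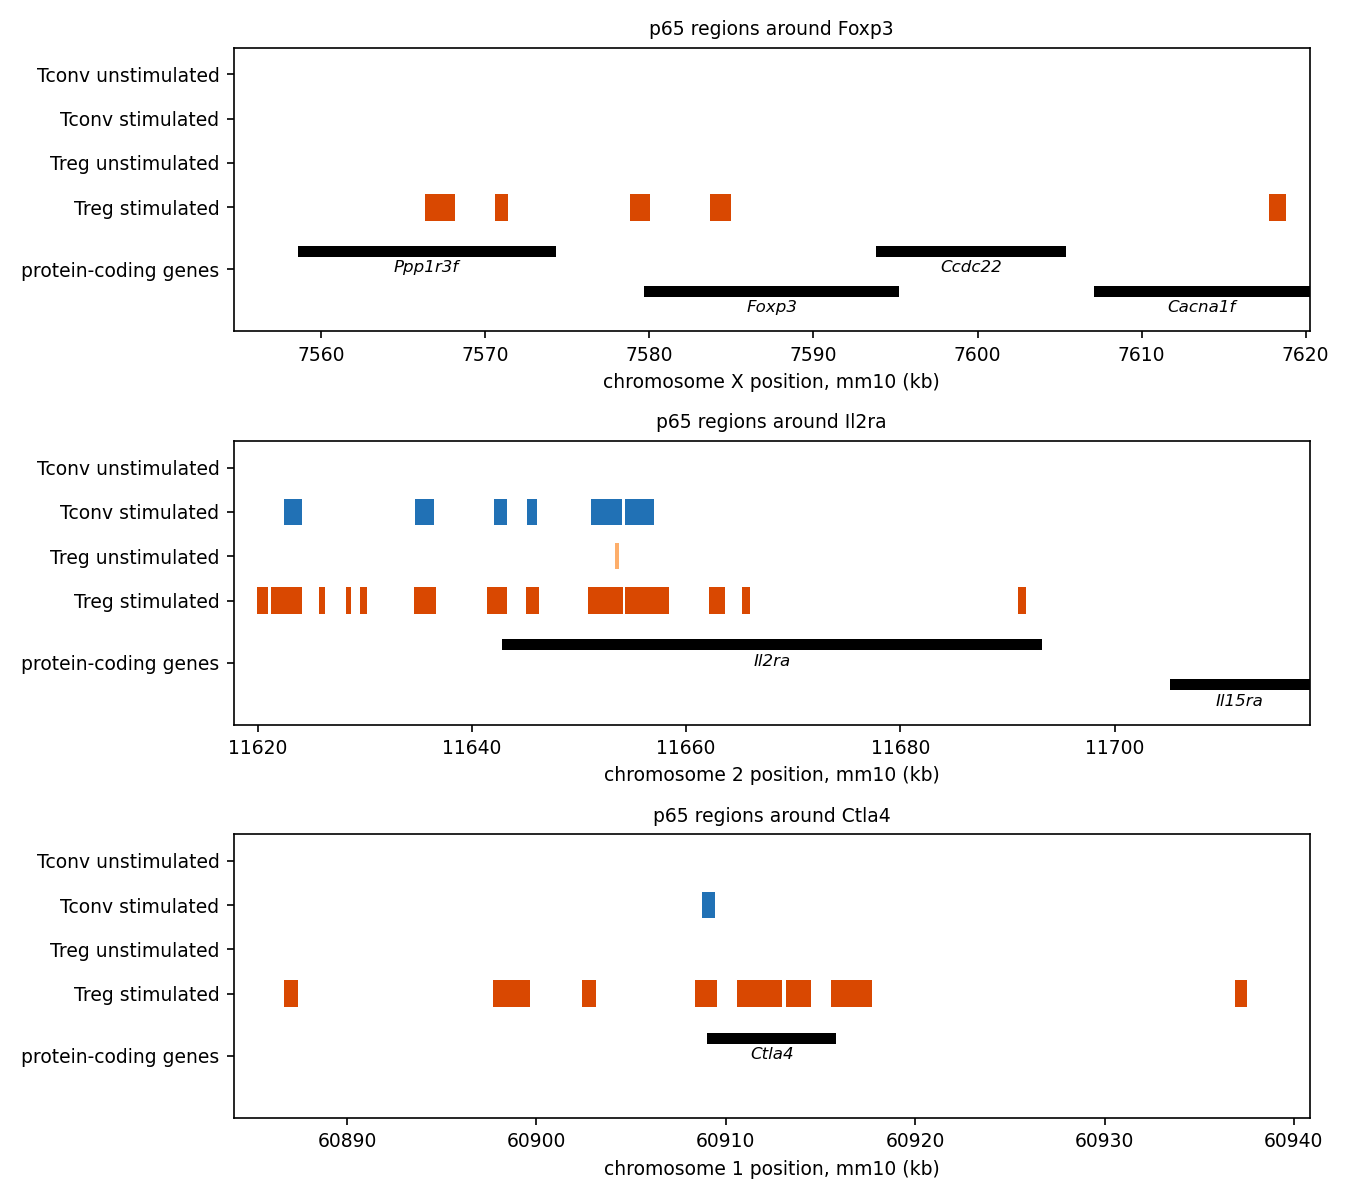
Maps of p65 regions (coloured bars, 1 row per peak list) around Foxp3, Il2ra and Ctla4, with protein-coding genes as black bars; the horizontal axis is the mm10 position in kb, with 25 kb shown on each side of the named gene. Regions assigned to Foxp3 appear in the stimulated Treg row alone, and Ctla4 has 8 regions there against 1 in stimulated Tconv.

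Crossing cell type with stimulation, 8329 merged regions of the stimulated lists overlapped neither unstimulated list. Of these, 4899 (58.8%, 57.8 to 59.9%) were in Treg alone, 3274 (39.3%) in both cell types and 156 (1.87%) in Tconv alone. With the 5734 strongest regions of each stimulated list by fold enrichment, and full unstimulated lists, the shares were 28.8% in Treg alone, 53.5% in both and 17.7% in Tconv alone.

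Markers of other cells were bound no more often than random genes. In stimulated Treg, 0 of 12 B cell markers (percentile 1.79), 2 of 15 myeloid and dendritic markers (18.1), 2 of 12 NK and cytotoxic CD8 markers (31.9) and 1 of 11 erythroid and endothelial markers (8.88) had a region, and 2 of 26 liver and neuron control genes (0.855). In the same order, the counts were 0, 2, 2, 1 and 1 in stimulated Tconv, 1, 2, 0, 2 and 1 in unstimulated Treg and 0, 2, 0, 2 and 0 in unstimulated Tconv. The ribosomal control list had regions more often than random lists, at 18 of 42 genes in stimulated Treg (above all 10000 random lists), 10 in stimulated Tconv (percentile 98.4), 13 in unstimulated Treg (99.995) and 11 in unstimulated Tconv (99.8).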

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

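The shares of regions with no counterpart across stimulation differed between the Treg and Tconv lists, in a test chosen after the result was seen. It compares regions of 1 pooled list per group, and the lists differ in length, so it does not show that the effect of stimulation differed between the cell types. Stimulated regions without an unstimulated counterpart made up 77.3% of the Treg list and 67.4% of the Tconv list, 9.89 percentage points more in Treg (odds ratio 1.65, two-sided Fisher's exact p = 1.13e-42). With regions of all lists at a −log10 p of 38.1 or more the difference was 5.49 points (87.4% and 81.9%, exact p = 4.81e-19), and with equal list lengths by fold enrichment the shares were 75.1% and 62.7%. Unstimulated regions without a stimulated counterpart made up 21.6% of the Treg list and 36.3% of the Tconv list, a difference of -14.7 points (odds ratio 0.483, exact p = 2.65e-37). At the common cut-off this difference turned to 9.53 points, with 28.0% in Treg and 18.5% in Tconv (Fisher's exact p = 4.44e-09). With equal list lengths the shares were 74.8% and 62.4%. Equal lengths make the shares of both directions nearly equal, so these values repeat the first difference and are not separate evidence. By the common cut-off, the direction of the second difference depends on where the lists end.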

How the results depend on the processing

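No paired analysis was possible because each deposited list pools both libraries of a group, so no fit with a replicate block and no list without a replicate was had. The motif alternatives were not run, since no genome sequence was used. Depth and the agreement between replicates are unknown, and their effects on list length were not removed. The common cut-off on −log10 p, the nearest gene end and the adjustment for strength were chosen after seeing the data. Where a share moved, the cause was not tested beyond what the alternative's construction shows. Equal lengths shorten the longer list and make the shares of both directions nearly equal.

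Percent without a counterpart, for stimulated Tconv against unstimulated and then the reverse, was 74.7 and 51.0 with reciprocal overlap, 70.1 and 39.5 with summits within 200 bp, 76.1 and 53.4 in the upper 50%, 62.7 and 62.4 with equal lengths by fold, 63.7 and 63.3 by −log10 p, and 81.9 and 18.5 at the common cut-off. The strongest stimulated regions against the full list gave 62.7. For Treg the same settings gave 81.2 and 35.2, 79.8 and 25.8, 85.2 and 48.4, 75.1 and 74.8, 76.1 and 75.8, and 87.4 and 28.0, with 72.9 for the strongest stimulated regions. For unstimulated Treg against Tconv and the reverse they were 25.3 and 19.1 (reciprocal), 17.3 and 10.3 (upper 50%), 17.8 and 17.8 (equal by fold), 16.9 and 16.8 (by −log10 p), and 19.1 and 7.18 (common cut-off), with 17.8 for the strongest Treg regions. For stimulated Treg against Tconv and the reverse they were 54.6 and 12.3, 51.1 and 4.90 (summits), 51.5 and 8.06, 30.8 and 31.5, 30.1 and 30.8, and 38.1 and 11.5, with 14.3 and 0.844 for the strongest regions.

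Regions gained in Treg alone made up 34.3% with equal lengths of all lists, 28.8% with equal stimulated lists, 56.7% in the upper 50% and 41.1% at the common cut-off. Near a gene end (unstimulated Tconv, stimulated Tconv, unstimulated Treg, stimulated Treg) were 78.8, 47.1, 76.7 and 41.0% within 2.5 kb, 77.1, 44.5, 75.3 and 38.2% with all biotypes, and, with equal lengths, 36.9% of stimulated Tconv and 22.7% of stimulated Treg regions.

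Of 751 gene list results under an alternative, 658 kept their side of the percentile limits, 69 lost a call, 24 gained one and 0 reversed. Lists without a main call were left out for unstimulated regions without a stimulated counterpart and for Tconv regions without a Treg one. Calls gained there are therefore not among the 24. The number of lists standing apart by genes with a region was 8 in unstimulated Tconv and 5 with the 10 kb distance. By regions without a counterpart, it went from 3 to 6 (every gene within 50 kb) and 1 (common cut-off) for unstimulated Tconv without stimulated Tconv, and from 4 to 2 (10 kb), 7 (every gene) and 2 (common cut-off) for stimulated against unstimulated Treg. The reverse went from 4 to 2 (no matching) and 1 (common cut-off). Unstimulated Treg without Tconv went from 4 to 0 at the common cut-off, and the reverse from 2 to 1 (10 kb), 0 (common cut-off) and 1 (adjusted for strength). Stimulated Treg without Tconv went from 5 to 3 (200 kb), 2 (equal lengths), 3 (every gene), 2 (no matching), 3 (common cut-off) and 3 (adjusted for strength), and the reverse from 0 to 1 (equal lengths) and 2 (common cut-off). The Treg identity list stood above random lists for stimulated Treg without Tconv in all 8 alternatives run.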

Other observations

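By the number of genes with a region, T cell receptor signalling genes had regions after stimulation at 23 of 24 genes in Treg and 22 in Tconv, against 10 and 7 without stimulation. Cytokine receptor and STAT genes had regions at 24 of 30 genes in stimulated Treg and 22 in stimulated Tconv, against 16 and 9. Co-stimulation genes had regions at 22 of 25 genes in stimulated Treg and 17 in stimulated Tconv, against 5 and 3. Each of these stimulated counts lay above all 10000 random lists. Standing above them was not particular to T cell genes, as random lists were matched on territory alone. The ribosomal control did so in stimulated Treg (18 of 42 genes) and lay at percentile 98.4 in stimulated Tconv. The liver and neuron control lay below random lists in both (percentiles 0.855 and 2.01). Naive and conventional T cell genes had regions at 21 of 25 genes in both stimulated lists, against 11 in unstimulated Treg and 12 in unstimulated Tconv. Survival genes had regions at 18 of 22 genes in stimulated Treg and 11 in stimulated Tconv, and chemokine receptor genes at 17 and 12 of 22. Class I antigen presentation genes had regions at 8 of 16 genes in stimulated Treg (percentile 99.5) and 6 in stimulated Tconv (99.0). Effector cytokine genes had regions at 10 of 23 genes in both stimulated lists (percentile 97.3 in Treg and 99.9 in Tconv).

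The region of Kpna1 on chromosome 16 (35982662 to 35984197, 41.1-fold, −log10 p 296) was the strongest of the 173 regions present in unstimulated Tconv alone.

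The tests of list cut-offs, of strength in other regions, of depth or signal of the stimulated libraries, of IL-2, of gene ends in unstimulated regions and of ribosomal genes in the unstimulated lists were chosen after the results they concern were seen. The first pattern is that 49.3% of stimulated Treg regions had no stimulated Tconv counterpart. A common p cut-off for the lists lowered the share to 38.1%. Whether different cut-offs account for the pattern cannot be told from this, since no like benchmark was at hand. The upper bound for the unstimulated pair there was 21.2%, but that pair is not a like benchmark. It held 1470 Treg and 1281 Tconv regions at that cut-off, against 8329 and 5734 in the stimulated pair. The more a list outnumbers the other, the more of its regions must lack a counterpart. If deeper or cleaner Treg libraries were the cause, strength alone would decide which regions lacked a counterpart, and near Treg identity genes it did not: 72.8% had no counterpart, the 100th percentile of draws matched on fold enrichment (median 39.5%, highest 53.1%), and 68.8 to 74.7% when any 1 gene of the list was left out. For the other regions the loss followed strength, with 4.17% of the strongest and 86.8% of the weakest of 10 equal parts without a counterpart, so a difference in depth or signal may account for many of them. The higher IL-2 of the Treg culture cannot be told apart from cell type, since 0 stimulated Treg libraries had the IL-2 concentration of the Tconv culture, and a difference between the cell types stays open as a hypothesis.

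The second pattern is that unstimulated regions lacked a stimulated counterpart. A stricter cut-off of the stimulated lists is not enough for it: with all lists at a −log10 p of 38.1 or more, 18.5% of 1281 Tconv regions (16.5 to 20.7%) and 28.0% of 1470 Treg regions (25.8 to 30.4%) lacked one, above the upper bounds of 8.73% and 21.2% for the unstimulated pair. Of the 740 strongest Tconv and 802 strongest Treg regions, 8.51% (6.71 to 10.7%) and 5.36% (4.005 to 7.14%) lacked one, between the bounds of 5% and 10% set beforehand for a cut-off, against 50.3% and 30.7% of the weakest. Lower depth or signal of the stimulated libraries stays open. The stimulated lists were longer although they end at a higher −log10 p, which goes against it. Their median folds were higher (12.8 against 8.49 in Tconv, 11.5 against 8.30 in Treg), as was the fold at 59.9% and 64.2% of shared regions. The higher cut-off of the stimulated lists can by itself raise these folds, so they do not decide. At the 471 and 628 strongest shared regions the median stimulated fold was 0.642 and 0.590 times the unstimulated one (0.982 and 0.979 within the unstimulated pair), which goes with it. Signal at open gene ends, rather than at regulated sites, could not be separated: 68.2% (63.9 to 72.2%) of the 475 regions in both unstimulated and neither stimulated list lay near a gene end, against 72.8% (70.6 to 74.9%) of regions in all lists; a loss of p65 binding on stimulation stays open, as untested.

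The third pattern is that ribosomal protein genes, chosen as a control, had regions more often than random genes. In the unstimulated lists, signal within 1 kb of the ends of protein-coding genes is not enough for it: with the other regions alone, the list lay at percentile 99.7 in Tconv (4 of 42 genes) and 99.95 in Treg (5 genes), and at 98.0 and 99.6 with 1 gene fewer. With regions more than 2.5 kb away alone, the percentiles were 97.1 (2 genes) and 99.4 (3 genes, 95.6 with 1 fewer), so signal reaching that far stays open. Transcription start sites inside genes and ends of non-coding genes were not told apart from other sites, so signal at them stays open as well. After stimulation, regions more than 1 kb away gave percentile 96.7 in Tconv (4 genes) and 97.8 in Treg (6 genes), which passed the upper limit set beforehand but would be 93.6 with 1 gene fewer, so signal at gene ends stays open there, by a rule added after the value was seen. No biological explanation was tested.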
